A study of Mus musculus with 6 samples.

How the data were processed

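RNA of sorted endothelial cells from mouse brain cultures was sequenced as polyadenylated libraries made, per the labels' protocols, with TruSeq RNA v2 or TruSeq Stranded mRNA reagents; the labels do not say which kit was used for which library. The authors deposited a table of raw counts for 52636 Ensembl gene identifiers and 6 libraries, and these whole-number counts per gene were used as deposited. Per the submitters' processing notes, FastQC 0.11.5 and STAR 2.7.6a were used with the genome build GRCm38. The counting program, its strand setting and the annotation release are not given in the sources used here. Reads of genes that overlap on opposite strands, or that share sequence with near-identical copies, could therefore have been split or merged by the counting, and this is given in the text for the genes that the naming rule below selected. The table held 0 rows that name no gene and 0 columns of other samples.

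Gene symbols, positions and exon overlaps were taken from the GENCODE M21 annotation of GRCm38. Of the 52636 identifiers 52403 matched, and the 233 without a match held at most 0.0446% of the counts of a library. For each named gene, the share of exonic bases that lie in exons of other genes was computed on either strand, as was the share of its 50-base transcript sequences that occur in transcripts of other genes.

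Groups and replicate numbers were taken from the sample titles, with 3 control and 3 knockout libraries. Library totals were 17274639 to 19410458 counts. Intervals from counts cover counting error only, since no molecular identifiers were recorded in the labels. No pair of libraries agreed within sampling noise (the lowest chi-square per degree of freedom was 5.80), and each was kept as a separate replicate.

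Expression was compared in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, leaving 13901, and libraries were scaled with TMM. Quasi-likelihood F tests (glmQLFit, glmQLFTest, two-sided, no covariate) were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM values used TMM-scaled library sizes. A ratio of counts is given in place of a fitted fold change for a called gene with 1 to 3 counts in a whole group, with an exact conditional binomial interval at 95%.

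The 25 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives except 2. The 16 main lists cover endothelial, signalling, inflammatory, matrix and stress genes, and the 9 others cover markers of other cell types and of dissociation stress. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the 25 lists, and member calls were counted over all genes and adjusted over the list alone. No list call held when camera estimated the correlation from the 6 libraries, or from the 5 without control 2. That form of the test rests on the few residual degrees of freedom of these libraries, so hardly any list could pass it after adjustment. The estimated correlation was 0.542 for endothelial identity but -9.811e-04, below the preset value, for the Notch list, and both lost their calls. A call lost in this form therefore does not show that the members of a list were correlated. Lists of markers share members with one another, and several check-list genes, such as Gja1, Acta2 and Hspa8, are also expressed by endothelial cells. Shares of mitochondrial (37) and ribosomal protein (89) genes were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 libraries.

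The genes named were Erg and Fli1, then the 5 genes with the largest positive and the 5 with the largest negative log2 fold change among called genes with a mean of at least 10 CPM and no overlap between the groups, leaving out gene models without a proper symbol. From each main list came the 2 members (4 for endothelial identity) with the largest absolute log2 fold change among called members with a mean of at least 5 CPM, and from each other list the member with the highest mean CPM. This gave 51 genes.

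Alternatives were RLE and upper-quartile scaling, library size only, DESeq2 1.42.0, limma voom, no filter on low counts, a stricter filter (1 CPM in 3 libraries), the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a test against a 1.5-fold change. For lists, camera with an estimated correlation, camera with ranks and fry were tried, and for the shares, leaving out the 20 most abundant other genes. Sample weights and a term for the sex of the cells, read from Xist and 4 Y-linked genes, were added after seeing the data.

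The gene test was tested on simulated counts with the means and library sizes of these libraries. With the dispersion of all 6 libraries (13650 genes), it recovered 20.4% of genes changed 2-fold and 80.6% of genes changed 4-fold, with 8 false calls among 107. With the dispersion estimated without control 2 (13695 genes), it recovered 78.1% and 94.9%, with 12 false calls among 181. Both simulations kept 3 libraries per group and differed only in the dispersion, so neither gives the recovery of the fit that leaves control 2 out. Far fewer genes were changed in the simulated counts than were called in the data. Counts were drawn independently for each gene and library, whereas control 2 differed from the other controls in many genes together. The rates therefore need not hold for these libraries.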

Results

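Gene expression was measured by RNA sequencing in endothelial cells grown from mouse brain. All cultures had received 4-hydroxytamoxifen, which activates an inducible Cre recombinase, and living cells were sorted as negative for CD45 and positive for CD31 and VE-cadherin, the proteins of Pecam1 and Cdh5. The 6 libraries formed 2 groups, 3 from wild-type control cells and 3 from cells deleted for Erg and Fli1 (called knockout here). Erg and Fli1 encode ETS-family transcription factors of endothelial cells, and the series asks how such factors maintain the adult endothelial fate. The libraries held 17274639 to 19410458 gene counts. Levels are given as CPM (counts scaled to a common library size) with the SD over n = 3 libraries per group.

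The libraries did not all come from 1 animal. Controls 1 and 3 and knockout 1 had 110 to 116 CPM of the Y-linked gene Ddx3y and at most 5.32 CPM of Xist, which is transcribed from the inactive X chromosome. Control 2 and knockouts 2 and 3 had 431 to 611 CPM of Xist and at most 0.391 CPM of Ddx3y. The controls thus held 2 male libraries and 1 female library, and the knockouts 1 male and 2 female. The labels do not say which libraries share a culture or an animal, so that p-values measure the spread between these libraries, part of which may be technical.

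Control 2 stood apart from controls 1 and 3. Its counts differed from theirs with a chi-square per degree of freedom of 190 and 173, against 5.80 between controls 1 and 3 and 9.17 to 10.6 between knockout libraries. Against the knockouts the values were 167 to 177 for control 2 and 179 to 219 for controls 1 and 3. By this measure control 2 was about as far from its own group as from the knockouts. Its log2 CPM correlated at 0.921 and 0.935 with controls 1 and 3 and at 0.907 to 0.920 with the knockouts. Transcripts of the fibroblast list were higher in control 2 than in the other controls by a median of 3.89 on the log2 scale, in 12 of 12 members with at least 5 CPM. Pericyte and smooth muscle genes were higher by 2.83, while endothelial identity genes had a median of -1.03 and interferon genes of -1.47. Col1a1, a fibrillar collagen gene, had 5489 CPM in control 2, 214 CPM in control 1 and 628 CPM in control 3. Rgs5, a pericyte marker, had 264 CPM in control 2 and 1.95 and 6.85 CPM in controls 1 and 3. Counts without control 2 are therefore given where they differ from those of all libraries.

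**Figure D1:**
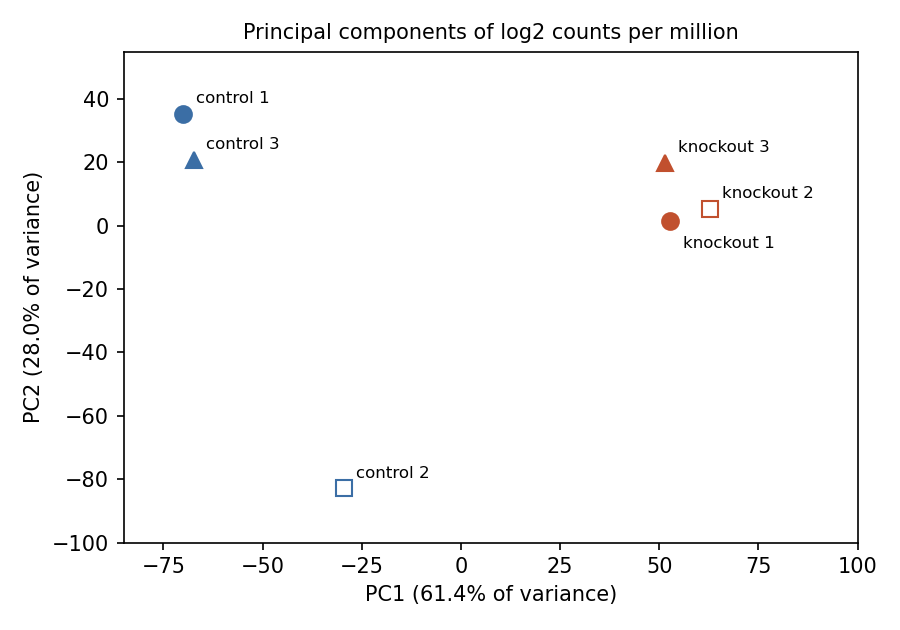
Principal components of log2 CPM over the tested genes, 1 point per library, in blue for controls and orange for knockouts. The first component (61.4% of the variance) separates the groups, with control 2 at -29.6 and controls 1 and 3 at -70.0 and -67.4. The second (28.0%) separates control 2, at -82.8, from the other libraries, which lie between 1.39 and 35.3.

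Erg transcripts fell in the knockout, whereas the change of Fli1 did not pass the test. Erg (ENSMUSG00000040732; GRCm38 chromosome 16, 95359169 to 95586593, minus strand) had 496 ± 238 CPM in controls and 89.3 ± 19.6 CPM in knockouts, 18.0% of the control mean. Its log2 fold change was -2.48 (SE 0.44, edgeR adjusted p = 0.0137), and each knockout library lay below each control. Control 2, at 223 CPM, had the lowest Erg level of the controls; without it the log2 fold change was -2.86 (edgeR adjusted p = 2.255e-05). Without control 3 or any 1 of the knockout libraries, the edgeR adjusted p was 0.0508 to 0.0691. Fli1 (ENSMUSG00000016087; GRCm38 chromosome 9, 32422204 to 32542861, minus strand) had 79.7 ± 14.3 CPM in controls and 64.1 ± 6.14 CPM in knockouts, with a log2 fold change of -0.32 (SE 0.15, edgeR adjusted p = 0.181). Without control 2 its log2 fold change was -0.48 (edgeR adjusted p = 0.00346). Exact two-sided permutation tests of the CPM values gave p = 0.1 for Erg, the smallest that 3 against 3 libraries allow, and p = 0.3 for Fli1. Counts were summed over whole genes, so transcripts that lack the deleted exons are counted as well.

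**Figure D2:**
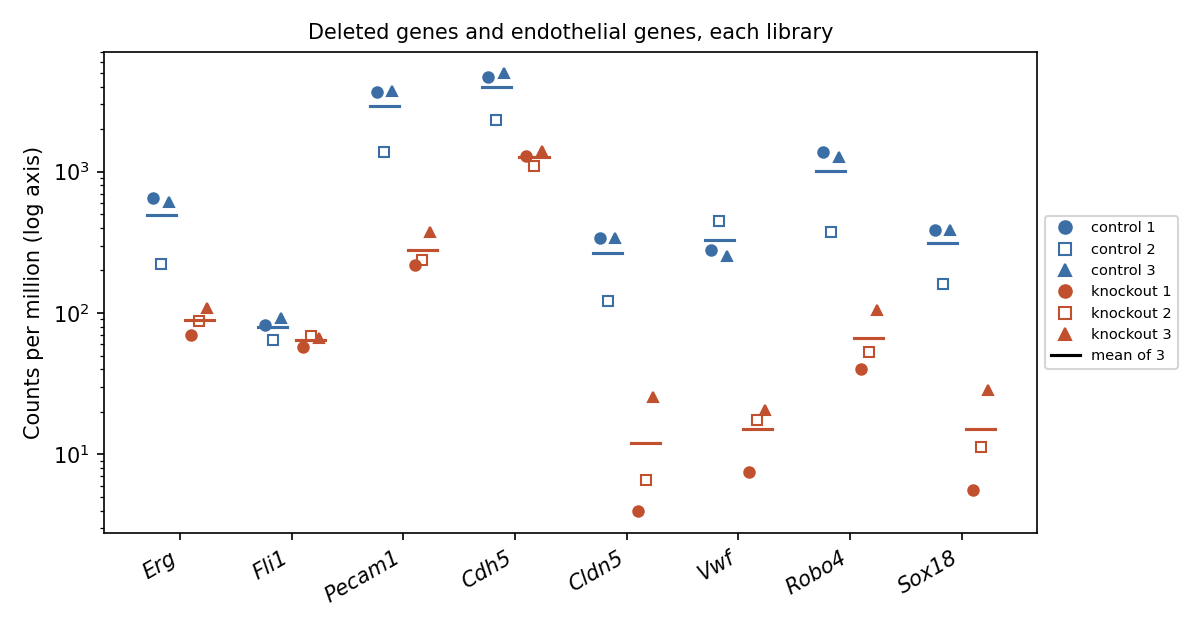
CPM on a log axis of the deleted genes Erg and Fli1 and of 6 endothelial genes, 1 symbol per library (filled circle, open square and filled triangle for replicates 1, 2 and 3), with a bar at each group's mean. Erg separates the groups, Fli1 overlaps between them, and Cldn5, Vwf, Robo4, Sox18, Pecam1 and Cdh5 are lower in every knockout library than in every control.

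The knockout altered 3437 of 13901 tested genes (edgeR, adjusted p under 0.05), of which 1816 were higher and 1621 lower. The genes that rose and fell furthest are given among called genes with a mean of at least 10 CPM and no overlap between the groups. Tnfsf8, encoding the CD30 ligand, had 24.1 ± 3.40 CPM in knockouts and 2 counts over the 3 controls, a ratio of 670 with a 95% counting interval of 185 to 5538. Both control counts lay in control 2, so without it no finite ratio is given. Hlf, a transcription factor gene of the PAR bZIP family, rose from 0.163 ± 0.056 to 73.2 ± 8.46 CPM (log2 fold change 8.76, SE 0.22, edgeR adjusted p = 3.607e-04). Ccl20, a chemokine gene, rose from 0.651 ± 0.568 to 254 ± 50.8 CPM. The glycosyltransferase gene Gcnt1 rose from 0.937 ± 0.288 to 80.1 ± 32.2 CPM, and the complement gene C3 from 4.77 ± 5.64 to 368 ± 63.7 CPM. Control 2 held most of the control C3, at 11.3 CPM against 1.95 and 1.10 CPM, and without it the log2 fold change moved from 6.27 to 7.87, and that of Ccl20 from 8.60 to 9.56. Above the same limit, the genes that fell furthest were Esm1, a tip-cell gene (605 ± 395 to 13.3 ± 11.001 CPM, log2 fold change -5.51, SE 0.99), Mall (83.4 ± 33.3 to 2.33 ± 2.11 CPM), F2rl2 (24.0 ± 19.5 to 0.867 ± 0.709 CPM), Abca4 (121 ± 47.2 to 4.78 ± 3.87 CPM) and Ltbp4 (134 ± 39.8 to 5.29 ± 1.77 CPM). F2rl2 had 1.63 CPM in control 2 and 33.5 and 36.9 CPM in controls 1 and 3, and its log2 fold change moved from -4.79 to -5.39 without control 2. F2rl2 encodes a protease-activated receptor and Ltbp4 a latent TGF-beta binding protein. Of these 10 genes, Esm1 lost its call without knockout 1 or 2 and Mall without knockout 2 (edgeR adjusted p up to 0.0735 and 0.0604). F2rl2 lost its call without control 1, control 3 or any 1 knockout library (up to 0.159). Knockout 3 had the highest remaining level of Esm1 (25.7 CPM against 4.73 and 9.37 CPM), Mall, F2rl2 and Abca4. Without it their log2 fold changes were -6.42, -6.14, -5.60 and -5.57.

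The split into higher and lower genes depended on the scaling, with 52.8% of calls higher after TMM normalization and 66.4% when only the library size was used (2501 higher, 1268 lower). Without control 2, 7128 genes passed, 3617 higher and 3511 lower, and these included 3415 of the 3437 calls in the same direction. Without control 1 the count was 1788 and without control 3 it was 1582. Without knockout 1, 2 or 3 it was 1467, 1351 and 1609.

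On GRCm38 the 5 genes that rose furthest above that limit of 10 CPM lie as follows: Tnfsf8 (ENSMUSG00000028362) on chromosome 4, 63831308 to 63861347, Hlf (ENSMUSG00000003949) on chromosome 11, 90336536 to 90390895, Ccl20 (ENSMUSG00000026166) on chromosome 1, 83116766 to 83119167, Gcnt1 (ENSMUSG00000038843) on chromosome 19, 17326141 to 17372844, and C3 (ENSMUSG00000024164) on chromosome 17, 57203970 to 57228136. Of the 5 that fell furthest above the limit, Esm1 (ENSMUSG00000042379) lies on chromosome 13, 113209659 to 113218098, Mall (ENSMUSG00000027377) on chromosome 2, 127704386 to 127729932, and F2rl2 (ENSMUSG00000021675) on chromosome 13, 95696853 to 95702739. Abca4 (ENSMUSG00000028125) lies on chromosome 3, 122044443 to 122180123, and Ltbp4 (ENSMUSG00000040488) on chromosome 7, 27305136 to 27337692. All 10 are annotated as protein-coding, and none shares exons with another annotated gene.

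Endothelial identity genes fell as a group. Of 30 tested members, 20 fell, 1 rose (Rhoj, 142 ± 14.03 to 251 ± 7.52 CPM) and 9 did not pass, with 22 lower and 1 higher when adjusted over the list alone. The camera test placed the list below other genes (adjusted p = 2.314e-09), a call that was lost with an estimated correlation (adjusted p = 0.433 with an estimated correlation). With these few libraries hardly any list could pass that form after adjustment, so the loss does not show that the members were correlated. Cldn5, the main claudin of the blood-brain barrier, fell from 266 ± 126 to 11.96 ± 11.6 CPM (log2 fold change -4.48, SE 0.87). Vwf, encoding von Willebrand factor, fell from 327 ± 107 to 15.2 ± 6.82 CPM, the guidance receptor gene Robo4 from 1008 ± 551 to 66.4 ± 34.5 CPM, and Rasip1 from 94.5 ± 25.8 to 5.82 ± 4.93 CPM. The transcripts of the sort markers also fell, Pecam1 from 2927 ± 1332 to 278 ± 85.4 CPM (edgeR adjusted p = 0.00665) and Cdh5 from 3985 ± 1460 to 1270 ± 153 CPM (edgeR adjusted p = 0.0168). Because cells were sorted as positive for both proteins, cells without them would not be among those measured. Control 2 had 1389 CPM of Pecam1, against 3655 and 3736 CPM in controls 1 and 3. For Cdh5 these were 2306 CPM against 4693 and 4957 CPM. Without control 2 the log2 fold changes of Pecam1 and Cdh5 moved from -3.40 and -1.65 to -3.77 and -1.96. Rhoj, Pecam1 and Cdh5 were picked out after their values were seen. In control 2 the list had a median of -1.03 (log2) relative to the other controls; without that library 28 members fell and 2 rose. Without control 1, control 3 or any 1 knockout library, 10 to 16 fell. Cldn5 lost its call without control 1, control 3, knockout 1 or knockout 2, Robo4 without knockout 1 or 2, and Rasip1 without knockout 2 (edgeR adjusted p up to 0.0810, 0.0622 and 0.0682). Knockout 3 held most of the remaining Cldn5, at 25.3 CPM against 3.96 and 6.64 CPM, and without it the log2 fold change of Cldn5 was -5.65 and that of Rasip1 -4.94. Annotated exons of other genes cover 20.4% of the Rasip1 exons on its own strand and 22.5% on the opposite strand, so its counts are uncertain.

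Endothelial transcription factor genes moved in both directions. Of 25 tested, 6 rose and 7 fell, with 7 higher and 9 lower when adjusted over the list alone, and the camera test did not separate the list from other genes (adjusted p = 0.440). The genes that rose were Tal1, Gata2, Foxc1, Foxf1, Foxf2 and Foxp1, named after their values were seen. Sox18, a SoxF-family factor of endothelial cells, fell from 312 ± 131 to 15.2 ± 12.03 CPM (log2 fold change -4.36, SE 0.73), and the homeobox gene Meox1 fell from 139 ± 67.6 to 11.3 ± 7.91 CPM. The control 2 median was -0.57 (log2) relative to the other controls, and without it 10 members rose and 12 fell; without any 1 of the other libraries 2 to 5 rose and 3 to 6 fell. Sox18 lost its call without knockout 2 and Meox1 without control 1, control 3, knockout 1 or knockout 2 (edgeR adjusted p up to 0.0641 and 0.0810). Knockout 3 had 28.7 CPM of Sox18 against 5.601 and 11.3 CPM, and without it the log2 fold changes of Sox18 and Meox1 were -5.21 and -4.32.

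Among 15 tested other ETS family genes, Ets1, Ets2, Elf1 and Elf2 rose and Etv4 and Elk3 fell; adjusted over the list alone 4 were higher and 3 lower. Ets2 rose from 113 ± 13.8 to 195 ± 6.68 CPM (log2 fold change 0.79, SE 0.10) and Etv4 fell from 78.0 ± 10.4 to 26.7 ± 4.39 CPM (log2 fold change -1.55, SE 0.16). The list did not stand apart (camera adjusted p = 0.872). Without control 2, 6 rose and 5 fell, and without any 1 of the other libraries 2 to 3 rose and 2 to 3 fell. Ets1, Elf1, Elf2 and Elk3 are named because of the small count, after their values were seen.

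Genes of the Notch pathway and of arterial endothelium fell more often than they rose. Of 22 tested, 10 fell and 4 rose (Nrp1, Bmx, Vegfc and Tm4sf1, named after their values were seen), the same numbers as when adjusted over the list alone. The camera test gave an adjusted p of 0.0146, and 0.364 was its adjusted p with an estimated correlation. Dll4, a Notch ligand gene, fell from 458 ± 113 to 18.9 ± 12.2 CPM (log2 fold change -4.60, SE 0.53). The chemokine receptor gene Cxcr4 fell from 216 ± 72.9 to 10.7 ± 11.8 CPM (log2 fold change -4.33, SE 0.89). The exons of Dll4 overlap those of an opposite-strand gene over 5.56% of their length. Nrp1 and Vegfc, which rose, encode a co-receptor and a ligand of the VEGF pathway. Without control 2, 11 fell and 5 rose and the list no longer passed (camera adjusted p = 0.176); without any 1 of the other libraries, 8 to 9 fell and 2 to 3 rose. Cxcr4 lost its call without control 1, control 3, knockout 1 or knockout 2 (edgeR adjusted p up to 0.0872). Knockout 3 had 24.3 CPM of Cxcr4 against 2.88 and 5.02 CPM, and 32.9 CPM of Dll4 against 12.8 and 10.9 CPM. Without it the log2 fold changes of Cxcr4 and Dll4 were -5.77 and -5.26.

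VEGF and angiopoietin signalling and sprouting genes included 14 that fell and 5 that rose of 30 tested; adjusted over the list alone, 17 were lower and 6 higher. The genes that rose were Nrp1, Nrp2, Vegfb, Vegfc and Hif1a, ligands, co-receptors and a hypoxia-response factor named after their values were seen. The list passed the camera test (adjusted p = 0.0246) but not with an estimated correlation (adjusted p = 0.393 with an estimated correlation), nor without control 2 (camera adjusted p = 0.0751). Besides Esm1, the potassium channel subunit gene Kcne3 fell from 19.0 ± 10.5 to 0.370 ± 0.548 CPM (log2 fold change -5.67, SE 1.05). Control 2 had a median of -0.64 (log2) for the list, and without it 17 fell and 12 rose; without any 1 of the other libraries 6 to 11 fell and 4 rose. Kcne3 exons overlap those of an opposite-strand gene over 0.51% of their length. Kcne3 lost its call without control 3, knockout 1 or knockout 2 (edgeR adjusted p up to 0.0642); 18 of its 20 knockout counts lay in knockout 3, without which its log2 fold change was -8.30. Esm1 lost its call without knockout 1 or 2 (up to 0.0735).

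Basement membrane and integrin genes fell in 8 of 26 tested cases and rose in 2 (Lama5 and Agrn, named after their values were seen), with 9 lower and 2 higher when adjusted over the list alone. Col15a1, encoding a basement membrane collagen, fell from 1455 ± 912 to 98.2 ± 31.3 CPM (log2 fold change -3.89, SE 0.54), and Nid2, encoding nidogen 2, from 350 ± 66.1 to 39.3 ± 5.39 CPM (log2 fold change -3.16, SE 0.18). The exons of Nid2 overlap those of Rtraf on the opposite strand over 8.45% of their length, and those of Col15a1 overlap an opposite-strand gene over 0.22%. The camera adjusted p was 0.0276; it was 0.433 as an adjusted p with an estimated correlation and 0.0797 without knockout 2. In control 2 Col15a1 stood at 2507 CPM, against 904 and 952 CPM in controls 1 and 3, and without it the log2 fold change was -3.27. Without control 2, 13 members fell and 6 rose.

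Inflammation and leukocyte adhesion genes rose as a group. Of 30 tested members, 18 rose and 0 fell (edgeR), and 21 rose when adjusted over the list alone; 22 were higher and 0 lower at an unadjusted p under 0.05, and 0 were lower with DESeq2 or limma voom. The camera adjusted p was 9.130e-13, against an adjusted p of 0.364 with an estimated correlation. Besides Ccl20, the chemokine gene Cxcl10 rose from 0.267 ± 0.263 to 10.5 ± 6.95 CPM (log2 fold change 5.25, SE 1.02, and 4.63 without control 2). Its exons overlap those of Art3 on the opposite strand over 5.91% of their length. Control 2 differed from the other controls in both directions for this list, with 16 members higher and 10 lower of 26 with at least 5 CPM, and 27 members rose without it. Without any 1 of the other libraries 13 to 16 rose, and Cxcl10 lost its call without control 3, knockout 2 or knockout 3 (edgeR adjusted p up to 0.0724), with log2 fold changes of 4.63 to 6.17 when 1 library was left out.

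Cell cycle genes rose in 25 of 30 tested cases, also when adjusted over the list alone, and 0 fell by edgeR (0 also at an unadjusted p under 0.05 and with DESeq2 or limma voom). The camera adjusted p was 2.642e-15, with an adjusted p of 0.364 with an estimated correlation. Bub1, a spindle checkpoint kinase gene, rose from 10.4 ± 0.707 to 41.6 ± 5.08 CPM (log2 fold change 2.00, SE 0.12), and the kinetochore gene Cenpf from 11.3 ± 1.42 to 40.8 ± 2.63 CPM (log2 fold change 1.86, SE 0.12). Both kept their calls in the 6 fits that left out 1 library each. Without control 2, 25 rose and 1 fell (Ccnd1, which had 1106 CPM in controls and 553 CPM in knockouts), and without any 1 of the other libraries 19 to 22 rose.

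Interferon response genes passed the camera test as a group (Up, adjusted p = 1.132e-04) although only 3 of 27 tested members were called, Ifit2, Mx2 and Zbp1, and 2 when adjusted over the list alone. With an estimated correlation the adjusted p was 0.786. Zbp1, encoding a sensor of nucleic acids, rose from 0.724 ± 0.309 to 17.6 ± 6.79 CPM (log2 fold change 4.59, SE 0.49), and Ifit2 from 4.74 ± 2.59 to 20.2 ± 3.59 CPM (log2 fold change 2.09, SE 0.40). Mx2 was named after its values were seen. Control 2 had the list at a median of -1.47 (log2) relative to the other controls. Without it the camera test gave an adjusted p of 0.0933, with 7 members higher; without any 1 of the other libraries 1 to 5 were higher. Ifit2 lost its call without control 1, control 3, knockout 2 or knockout 3 (edgeR adjusted p up to 0.0680).

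**Figure D3:**
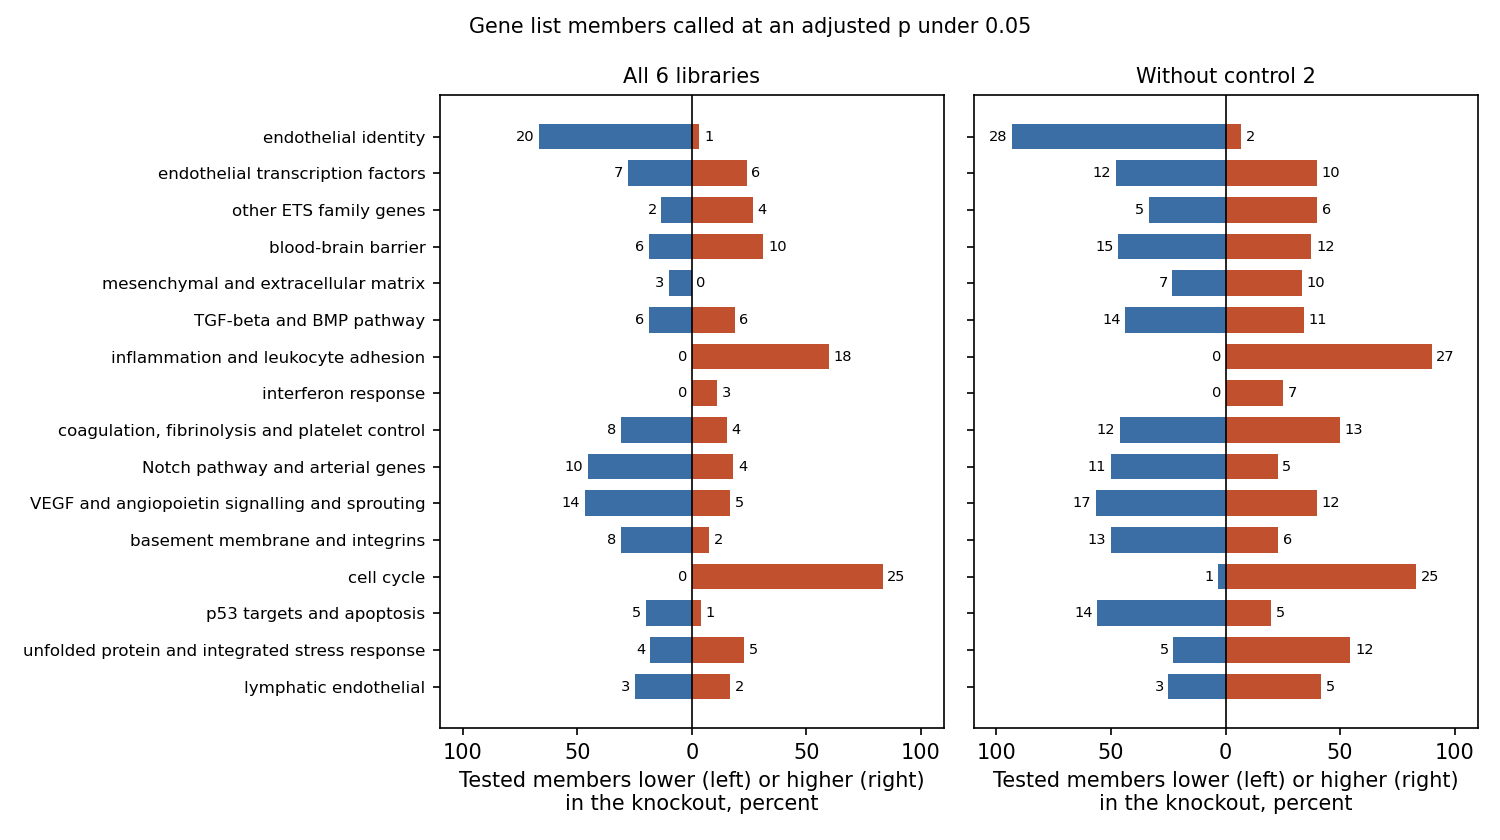
Percent of the tested members of each of 16 gene lists that were lower (blue, left) or higher (orange, right) in the knockout at an edgeR adjusted p under 0.05, with the number of members beside each bar, from all 6 libraries and without control 2. Endothelial identity has 20 and 28 lower members in the 2 panels, and inflammation and leukocyte adhesion 18 and 27 higher ones.

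Blood-brain barrier genes were mixed, with 10 higher and 6 lower of 32 tested (10 and 9 adjusted over the list alone, camera adjusted p = 0.773). Slco1c1, Slc22a8, Slc38a5 and Cgn had means of at most 0.127 CPM in controls and were not tested. Mfsd2a had 0.706 CPM in controls. For these members, named after their values were seen, little expression was left that could fall. Cldn5 fell as given above (edgeR adjusted p = 0.0174, and up to 0.0810 with control 1, control 3, knockout 1 or knockout 2 left out), whereas the forkhead gene Foxq1 rose from 1.10 ± 0.570 to 17.9 ± 2.38 CPM (log2 fold change 4.02, SE 0.38). An opposite-strand gene covers 66.1% of the Foxq1 exons, so reads of the pair cannot be told apart if counting ignored the strand. Without control 2, 12 rose and 15 fell, and without any 1 of the other libraries 7 to 8 rose and 2 to 3 fell.

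Mesenchymal and extracellular matrix genes did not pass as a group (camera Down, adjusted p = 0.116). Of 30 tested, 0 rose and 3 fell, also when adjusted over the list alone: Vim, Sparc and Tnc, the last named after its values were seen. At an unadjusted p under 0.05, 0 were higher and 7 lower, and 0 were higher with DESeq2 or limma voom. Vim, encoding vimentin, fell from 6485 ± 751 to 2272 ± 41.8 CPM (log2 fold change -1.51, SE 0.14) and the matrix gene Sparc from 5959 ± 259 to 2799 ± 183 CPM (log2 fold change -1.09, SE 0.12). Control 2 had the list at a median of 2.23 (log2) above the other controls. Without it 10 members rose and 7 fell, the median log2 fold change was -0.09 and the camera test pointed up (adjusted p = 0.791). Without control 1 or control 3 the list passed as lower (camera adjusted p = 0.00470 and 0.0266). It also passed as lower with library size only (0.0254), with DESeq2 (0.00891) and with a term for the sex of the cells (0.0249). Control 2 was the only female control, so among controls that term cannot be told apart from the difference of control 2.

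TGF-beta and BMP pathway genes rose in 6 and fell in 6 of 32 tested cases (7 and 6 adjusted over the list alone; camera adjusted p = 0.773). Gdf15, a divergent TGF-beta family cytokine gene, rose from 7.01 ± 4.85 to 49.4 ± 5.02 CPM and Id2, an inhibitor of helix-loop-helix factors, from 8.33 ± 4.39 to 33.4 ± 5.01 CPM. Without control 2, 11 rose and 14 fell, and without any 1 of the other libraries 2 to 3 rose and 1 to 2 fell. Gdf15 lost its call without control 1, control 3 or any 1 knockout library, and Id2 without control 1, knockout 1 or knockout 2 (edgeR adjusted p up to 0.0865 and 0.0658).

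Coagulation, fibrinolysis and platelet control genes rose in 4 of 26 tested cases (Tfpi, Pros1, Plau and Serpind1, named after their values were seen) and fell in 8, the same numbers as when adjusted over the list alone (camera adjusted p = 0.488). Besides Vwf, F2rl3, encoding the protease-activated receptor PAR4, fell from 14.1 ± 4.64 to 1.06 ± 0.578 CPM (log2 fold change -3.72, SE 0.51). Of the 50-base sequences in F2rl3 transcripts, 8.22% also occur in transcripts of other genes. Without control 2, 13 rose and 12 fell, and without any 1 of the other libraries 3 to 4 rose and 5 to 6 fell.

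p53 target and apoptosis genes fell in 5 of 25 tested cases (Bcl2l11, Cdkn2b, Cdkn1a, Bcl2 and Mcl1) and Bcl2l1 rose, the same numbers as when adjusted over the list alone; the list did not pass (camera adjusted p = 0.137). The pro-apoptotic gene Bcl2l11 fell from 59.9 ± 5.42 to 22.1 ± 1.60 CPM and the cell cycle inhibitor gene Cdkn2b from 94.6 ± 27.0 to 40.0 ± 6.62 CPM. Cdkn1a, Bcl2, Mcl1 and Bcl2l1 were named after their values were seen. Without control 2, 5 rose and 14 fell; without any 1 of the other libraries at most 1 rose and 1 fell. Cdkn2b lost its call without control 1, control 3 or any 1 knockout library (edgeR adjusted p up to 0.0827).

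Unfolded protein and integrated stress response genes rose in 5 of 22 tested cases (Ddit4, Herpud1, Dnajb9, Sdf2l1 and Ppp1r15a) and fell in 4 (Trib3, Asns, Chac1 and Atf3), with 5 in each direction when adjusted over the list alone. The list did not pass (camera Up, adjusted p = 0.773), and its median and mean log2 fold changes were 0.19 and -0.03. Trib3 fell from 43.6 ± 13.3 to 12.3 ± 1.44 CPM and Ddit4 rose from 44.3 ± 10.5 to 107 ± 15.7 CPM. The other members were named after their values were seen. Without control 2, 12 rose and 5 fell; without any 1 of the other libraries 5 rose and 3 to 4 fell.

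Of 12 tested lymphatic endothelial genes, Ptx3 and Sema3d rose and Flt4, Sema3a and Itga9 fell, with 3 in each direction when adjusted over the list alone (camera Up, adjusted p = 0.773). Ptx3, encoding the soluble pattern receptor pentraxin 3, rose from 32.6 ± 5.57 to 1177 ± 126 CPM (log2 fold change 5.17, SE 0.18). Sema3d rose from 10.6 ± 12.7 to 117 ± 16.9 CPM, with 25.2 CPM in control 2 and 2.95 and 3.62 CPM in controls 1 and 3, and its log2 fold change of 3.46 became 5.12 without control 2. Control 2 had the list at a median of 1.35 (log2); without it 5 rose and 3 fell, and the list passed (camera Up, adjusted p = 0.0424), but not with an estimated correlation (adjusted p = 0.551). Without any 1 of the other libraries 1 rose and at most 2 fell. Sema3d lost its call without control 1, control 3 or any 1 knockout library (edgeR adjusted p up to 0.121). Flt4, Sema3a and Itga9 were named after their values were seen.

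Markers of other cell types were examined in 9 lists. Fibroblast and meningeal genes did not pass (camera Up, adjusted p = 0.846, with median and mean log2 fold changes of -0.62 and -0.79); of 14 tested, Pdgfra rose and Aldh1a2 fell, also when adjusted over the list alone, and without any 1 library other than control 2, 1 rose and 0 fell. Without control 2, 8 rose and 2 fell and the list passed (camera Up, adjusted p = 0.00165), but not with an estimated correlation (adjusted p = 0.551). Dcn had 3.95 and 6.96 CPM in controls 1 and 3, 317 CPM in control 2 and 1625 ± 422 CPM in knockouts. Col1a1, the most abundant member, had 150 ± 73.8 CPM in knockouts, with a log2 fold change of -3.82 (SE 1.29, edgeR adjusted p = 0.0830) and of -1.52 without control 2 (edgeR adjusted p = 0.0406). Of 16 pericyte and smooth muscle genes Mylk rose and Abcc9 fell, and 0 of either when adjusted over the list alone (camera Down, adjusted p = 0.910); without control 2, 7 rose and 1 fell. Acta2, encoding smooth muscle actin, had 768 ± 321 CPM in knockouts and 3049 CPM in control 2 against 379 and 462 CPM in controls 1 and 3, and its log2 fold change of -0.76 (SE 0.87, edgeR adjusted p = 0.566) became 0.83 without control 2 (edgeR adjusted p = 0.0592).

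**Figure D4:**
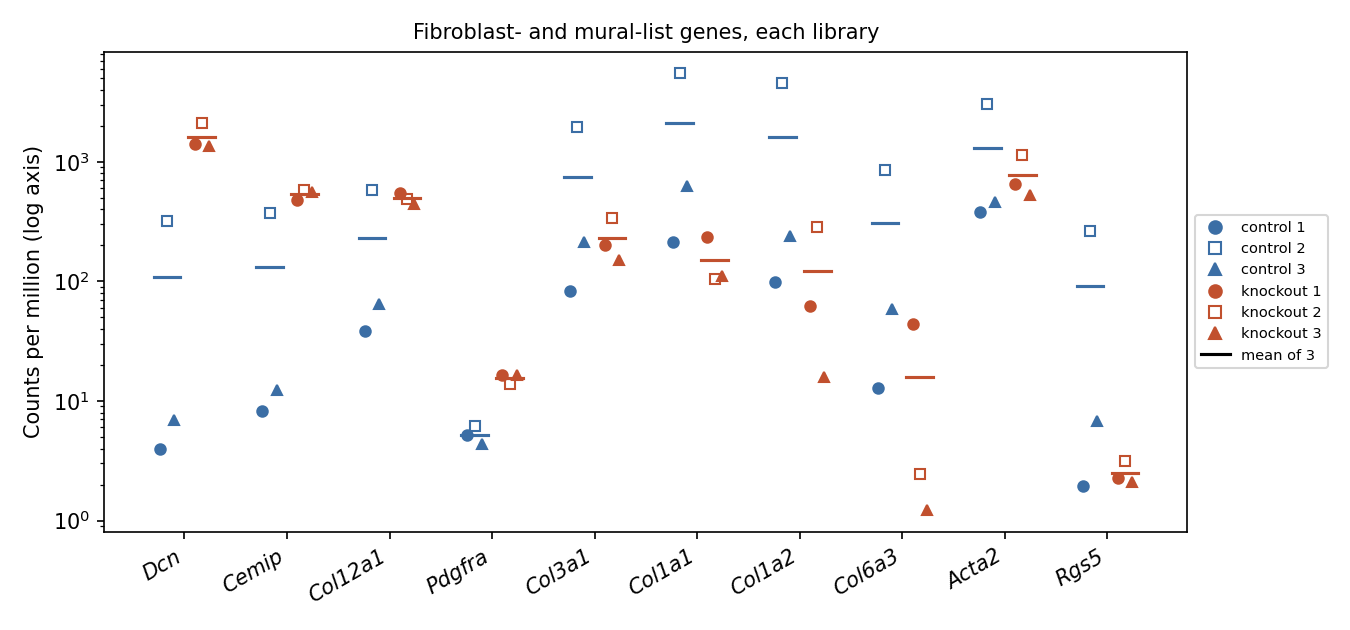
CPM on a log axis of 10 fibroblast, pericyte and smooth muscle list genes, 1 symbol per library (filled circle, open square and filled triangle for replicates 1, 2 and 3), with a bar at each group's mean. Control 2 lies above controls 1 and 3 for each gene, and the knockouts lie above it for Dcn but far below it for Col1a1.

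Of the remaining lists, dissociation stress genes passed (camera Up, adjusted p = 0.00324), a call lost with an estimated correlation (adjusted p = 0.364 with an estimated correlation). In this list 7 of 20 rose and Hsph1 fell (9 and 1 adjusted over the list alone), and without control 2, 13 rose and 3 fell, whereas without any 1 of the other libraries 3 to 5 rose and 0 fell. Its most abundant member, Hspa8, had 881 ± 57.7 CPM in controls and 756 ± 28.5 CPM in knockouts (edgeR adjusted p = 0.120, and 0.00333 without control 2); 38.6% of its 50-base sequences occur in other genes and same-strand genes cover 6.09% of its exons, so its counts are uncertain. Choroid plexus and epithelial genes had 4 of 6 members higher (Enpp2, Krt18, Cldn1 and Cldn2) and 1 lower, Clic6, which fell from 186 ± 38.2 to 14.7 ± 4.71 CPM; the list did not pass (camera Up, adjusted p = 0.137) until control 2 was left out (0.0172, and 0.409 with an estimated correlation), and 1 to 3 members rose without any 1 of the other libraries. Of 6 microglia and leukocyte genes, Laptm5 fell from 124 ± 67.9 to 27.3 ± 2.14 CPM and 0 rose, also at an unadjusted p under 0.05 (camera Down, adjusted p = 0.184, and without control 2 0.0111, or 0.470 with an estimated correlation). Without control 2, 0 rose and 2 fell. Laptm5 lost its call without control 1, control 3 or any 1 knockout library (edgeR adjusted p up to 0.106). Adjusted over the list alone, choroid plexus genes numbered 4 higher and 1 lower, and microglia genes 0 and 1.

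Astrocyte genes included Gja1 (183 ± 99.5 to 57.2 ± 9.98 CPM), the only one of 10 tested that was called, and 0 passed when adjusted over the list alone (camera Down, adjusted p = 0.773); without control 2, 4 rose and 2 fell. Of 3 oligodendrocyte genes Mbp rose and Cnp fell (60.0 ± 17.5 to 23.8 ± 1.74 CPM), also when adjusted over the list alone (camera Down, adjusted p = 0.773, with median and mean log2 fold changes of -0.59 and 0.55). The exons of Cnp overlap those of Dnajc7 on the opposite strand over 4.23% of their length. Of 6 neuronal genes Nefm fell, also when adjusted over the list alone (camera Down, adjusted p = 0.232), and without control 2, with 7 tested, 2 rose and 3 fell. Tubb3 had 32.9 ± 27.3 CPM in controls and 63.7 ± 12.2 CPM in knockouts (log2 fold change 0.95, edgeR adjusted p = 0.279). Without control 2, which had 64.1 CPM against 13.8 and 20.9 CPM, these were 1.84 and 4.684e-04. Of 3 erythroid and platelet genes Pf4 rose, also when adjusted over the list alone (camera Up, adjusted p = 0.660, with median and mean log2 fold changes of -0.38 and 0.67), and Itga2b had 2.58 ± 0.937 CPM in controls and 1.98 ± 0.369 CPM in knockouts. Gja1 lost its call without control 3 or any 1 knockout library and Cnp without any 1 knockout library (edgeR adjusted p up to 0.126 and 0.0648). List members named here beyond the most abundant ones were named after their values were seen.

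Mitochondrial genes took 2.59 ± 0.593% of counts in controls and 1.80 ± 0.133% in knockouts (exact two-sided permutation p = 0.1, the smallest possible), and control 2, at 1.92%, was the lowest control. Ribosomal protein genes took 1.68 ± 0.174% and 1.87 ± 0.034% (exact permutation p = 0.3). The 20 most abundant genes held 12.3 ± 0.912% of control and 9.15 ± 0.086% of knockout counts (exact permutation p = 0.1).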

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

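The sample weights and the term for the sex of the cells were chosen after seeing the data, and all other alternatives before. Erg kept its direction and its call, and endothelial identity (lower), inflammation and cell cycle (higher) kept theirs, under every scaling, filter and tool. Calls were lost for Erg with 1 library left out or at an adjusted p under 0.01, and for the 3 lists with an estimated correlation. The edgeR adjusted p of Erg was 0.0137 in the main fit, 0.0439 with the replicate block and 0.0493 with the sex term. Of the results tested per named gene, 491 stayed on their side of the threshold under alternatives that kept all libraries, 13 lost the call, 5 gained it and 1 reversed. Of the 51 named genes 45 were called in the main fit, and most were picked for large changes, which favours such stability. Over all genes, the same alternatives lost from 2 (sample weights) to 1621 (replicate number as a block) of the 3437 calls. Depth was similar between libraries, and the spread between the controls limits what can be called. With 3 simulated libraries per group, the recovery of 2-fold changes was 20.4% at the dispersion of all 6 libraries. It was 78.1% at the dispersion estimated without control 2. The simulated genes were independent, so neither rate models a shift of many genes together in control 2. The cause of the changes listed here was not tested unless given.

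The total of 3437 genes (1816 higher, 1621 lower) ranged from 1351 to 7128 with 1 library left out (803 to 3617 higher, 548 to 3511 lower), the highest of these without control 2. It was 1256 (732 and 524) at an adjusted p under 0.01 and 982 (540 and 442) against a 1.5-fold change, both stricter by construction. With sample weights, which gave control 2 a weight of 0.116, it was 7387 (4008 and 3379). With the sex of the cells as a term it was 2623, and with DESeq2 4375. Control 2 was the only female control, so among controls the sex term cannot be told apart from the difference of control 2.

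With the replicate number as a block (replicate block), 1844 genes passed (1038 higher, 806 lower), 1816 of them shared with the fit without it. Same-numbered libraries deviated from their group means with correlations across genes of -0.17, 0.16 and 0.25, so the numbers were not taken to pair the samples, and of the 3 controls only control 3 correlated best with its own number. The pericyte list turned upward under the block (adjusted p = 0.883).

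With 1 library left out, the Erg log2 fold change ranged from -2.86 to -2.24 and that of Fli1 from -0.48 to -0.22; the latter was -0.46 with sample weights, past the threshold (adjusted p = 0.00545). Acta2 ranged from -1.19 to 0.83, and was 0.65 with sample weights.

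For list tests the values are camera adjusted p unless another test is named. Hardly any list could pass with an estimated correlation. In that form the calls ended for Notch, cell cycle and inflammation (0.364), VEGF (0.393), endothelial identity and basement membrane (0.433) and interferon (0.786). With ranks they ended for Notch and VEGF (0.0741) and basement membrane (0.105). With fry, interferon did not pass (0.131) while p53 targets (0.0195), microglia (0.0289) and choroid plexus genes (0.00154) did. With sample weights the calls ended for Notch (0.114), VEGF (0.140), basement membrane (0.0950) and interferon (0.0814), while blood-brain barrier (0.760), other ETS genes (0.980), astrocyte (0.870) and pericyte (0.174) changed direction. Mesenchymal genes passed as lower with DESeq2 (0.00891), library size only (0.0254) and the sex term (0.0249). Without passing, the fibroblast list changed direction with DESeq2 (0.882), library size only (0.847) and the sex term (0.947), stress response genes with the sex term (0.947), pericyte genes with RLE (0.975), limma voom (0.805) and no filter (0.935), and other ETS genes with no filter (0.530).

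With 1 library left out, the list values ranged from 0.00470 to 0.791 for mesenchymal genes, 3.955e-10 to 0.0933 for interferon, 0.00590 to 0.176 for Notch, 0.0150 to 0.0751 for VEGF, 0.0111 to 0.0797 for basement membrane and 0.0424 to 0.872 for lymphatic genes; lymphatic genes passed only without control 2. Directions changed within ranges of 0.798 to 0.939 for other ETS genes, 0.446 to 0.771 for blood-brain barrier, 0.593 to 0.937 for stress response, 0.176 to 0.997 for pericyte, 0.00165 to 0.937 for fibroblast, 0.538 to 0.905 for astrocyte and 0.135 to 0.791 for neuron genes.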

Other observations

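The gene families and the tests in this part were chosen after the results were seen, except the count of other splits of the libraries.

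Of 14 gene families picked by symbol, 3 passed the camera test as higher in the knockout (complement, chemokines and the MHC class I pathway), none of them with an estimated correlation. That form of the test is one that hardly any list could pass with these few libraries. Of 16 complement components and regulators tested, 7 rose and 1 fell, against 10 and 1 without control 2 (camera adjusted p over the 14 families = 0.0367, and 0.659 with an estimated correlation; median log2 fold change 2.14, and 3.12 without control 2). Besides C3, Clu, encoding clusterin, rose from 23.5 ± 13.4 to 343 ± 82.7 CPM (n = 3; edgeR adjusted p = 0.00735). The member that fell was Cd55, a complement inhibitor of the cell surface, from 38.0 ± 27.3 to 4.21 ± 1.81 CPM (edgeR adjusted p = 0.0171). Control 2 had 69.4 CPM of Cd55, against 19.7 and 24.8 CPM in controls 1 and 3. Without it the log2 fold change of Cd55 moved from -3.17 to -2.43. Of 15 CCL and CXCL chemokine genes 8 rose and 0 fell by edgeR, against 12 and 1 without control 2 (camera adjusted p = 6.872e-06, and 0.491 with an estimated correlation; median log2 fold change 2.47), among them Cxcl5, from 18.1 ± 10.2 to 652 ± 112 CPM, and Ccl2, from 248 ± 40.5 to 1370 ± 147 CPM. Cxcl12, in contrast, had 1251 ± 594 CPM in controls and 509 ± 41.6 CPM in knockouts (edgeR adjusted p = 0.0659, and 1.126e-05 without control 2, which itself had 565 CPM). Ccl2, Ccl5, Ccl7, Ccl20, Cxcl1, Cxcl2, Cxcl5, Cxcl10 and Cxcl16 also belong to the inflammation list. The chemokine result is therefore not separate from that of the list.

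Of 20 genes picked by symbol for the MHC class I pathway, which include the class II pathway gene H2-DMa (not called), 9 rose and 0 fell by edgeR, against 14 and 0 without control 2 (camera adjusted p = 6.872e-06, and 0.659 with an estimated correlation; median log2 fold change 1.12). B2m, the invariant light chain, rose from 596 ± 176 to 1296 ± 123 CPM (edgeR adjusted p = 0.0226) and the peptide transporter gene Tap1 from 27.9 ± 3.76 to 55.8 ± 9.26 CPM (edgeR adjusted p = 0.00978). The H2 genes share sequence with one another, and their individual counts are uncertain. Each change of scaling moved the 3 medians by nearly the same small amount, so that they stayed above 0 is no support. Without control 2 the camera adjusted p at the preset correlation was 1.583e-08, 0.00363 and 2.139e-10 for complement, MHC class I and chemokines. The other 11 families did not pass (camera adjusted p 0.158 to 0.868).

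Control 2 stood apart from the other controls, with fibroblast and mural genes higher and most endothelial genes lower. A swap or mixture with a knockout library is argued against, because of 37 genes below 1 CPM in controls 1 and 3 and at 10 CPM or more in knockouts, the lower quartile of the control 2 level was 3.49% of the knockout level and the median 15.5%. The sex of the cells is argued against as the whole of it: the female minus male difference among knockouts had an SD of 0.24 (log2) over 10536 genes, against 0.86 for control 2 minus the male controls, and the 2 correlated across genes with r = -0.32. Cells of a fibroblast or mural type that passed the sort may have contributed, since endothelial identity genes were lower by a median log2 ratio of -1.03 with an interquartile range of -1.41 to -0.62, while the most abundant fibroblast genes, Col1a1 and Col1a2, reached 5489 and 4523 CPM. A CD31 and VE-cadherin gate is meant to exclude such cells, but the purity of the sort was not measured here. The interquartile range spanned 0.79, within the limit of 1 set for about 1 common factor. The endothelial members still differed: they ran from -2.17 for Cd34 to 0.76 for Vwf, with 26 lower and 4 higher. Interferon genes, with a median of -1.47, were lower still. Another state of the endothelial cells in that culture was not tested and stays open.

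Fibroblast-list genes were higher in knockouts than in controls 1 and 3, with 8 of 14 higher and 2 lower when control 2 was left out. Carry-over of the kind of cells whose transcripts are high in control 2 is argued against, because such cells would bring their most abundant transcripts, and Col1a1 stood at 150 ± 73.8 CPM in knockouts against 5489 CPM in control 2, while Dcn stood at 1625 ± 422 against 317 CPM. The 4 members most abundant in control 2 went both ways without it (Col1a1 -1.52, SE 0.50; Col6a3 -1.18, SE 1.27; Col1a2 -0.51, SE 0.98; Col3a1 0.61, SE 0.45), with a median log2 fold change of -0.84. The log2 ratio of knockouts to control 2 ran from 2.33 for Dcn to -7.14 for Col6a3 over the list, and with all libraries only Pdgfra was called higher. A change within the sorted cells through the deletion was not tested, and it stays open, as do cells of another kind.

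Fli1 counts stayed at 80.3% of the control mean while Erg counts stayed at 18.0%. Cells that escaped both deletions are argued against as the reason for this difference, since they would leave Erg at about the same percent as Fli1. Transcripts that keep the undeleted exons of Fli1, and cells in which only Erg was deleted, stay open, because counts are summed over whole genes. Escaped cells as a source of the remaining Erg were not tested and stay open. Erg was highest in knockout 3, at 109 CPM against 70.2 and 88.3 CPM in knockouts 1 and 2. Of the knockouts, knockout 3 also held the most Esm1, Cldn5 and Sox18, whereas knockout 1 held the most Ltbp4 and Col15a1. The groups of the design give deletion as the biological factor for both genes.

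The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of them, the genotype split, called as many as 3437 genes; the highest of the other splits called 3. With 10 splits no share under 0.05 can be reached.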
